A study of Mus musculus with 20 samples.

How the data were processed

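RNA-seq was done on whole mouse ovaries (B6D2F1) from embryonic day 18.5 (E18.5) and the day of birth (P0), in 20 libraries. The labels give Figla knockout and control ovaries at both ages and Lhx8 knockout and control ovaries at P0. The values are raw counts of reads per gene, deposited as 1 table per library with 49585 genes each. Per the labels' protocols, messenger RNA was selected from total RNA, the Figla libraries were made from double-stranded cDNA with a Nextera kit, and the Lhx8 libraries were made with the QuantSeq 3' kit, which reads the end of each transcript. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with HISAT2 to GRCm38.p5; their versions are not given in the sources used here. Per the file headers, the counts were made with featureCounts 1.6.0 on GENCODE M12 with strand ignored and no option for reads that map to several places.

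These choices set limits on what a count means. The Nextera libraries carry no strand, and the QuantSeq libraries do but were counted without it, so reads of a gene and of an overlapping antisense gene were added together. Counts of close paralogs, among them the Nlrp4, Nlrp9, Oas1, Obox and Fbxw families and the globin genes, are uncertain because reads shared between copies could be lost or assigned to another copy. No molecular identifiers are recorded, so intervals and count floors cover counting error only. The labels do not say which ovaries came from separate animals or litters, so p-values measure the spread between these samples, which may be technical in part. The 2 kits count different parts of a transcript, and no model held both knockouts.

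The labels conflict. The title, source and genotype fields list controls and then knockouts in order, while the library name in the description field, which is also the name the count table carries, alternates between them in the Figla set and is reversed in the Lhx8 set. The 2 sets of labels disagree for 6 of 14 Figla libraries and 6 of 6 Lhx8 libraries. Libraries were grouped by the library name, a choice made before the data were examined, as were the tests, the gene lists and the rule for naming genes. Grouping by title, and keeping only the libraries with agreeing labels, were alternatives. The genotype field calls the controls heterozygous and the Lhx8 library names call them wild type, so they are called controls here. Replicate numbers of the Figla libraries follow the order of deposit, as do the serial numbers in their library names, in which a control and a knockout alternate. They were not used to pair samples. Replicate numbers of the Lhx8 libraries are in the library names.

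Replicates were compared by a chi-square test over genes with at least 50 counts. E18.5 control replicates 1 and 2 differed by a chi-square of 1.12 per degree of freedom (p = 2.95e-21), and E18.5 knockout replicates 1 and 2 by 1.32 (p = 1.79e-134). The 22 other pairs within groups ranged from 6.62 to 62.3. The test therefore did find a difference within both near-identical pairs, but a far smaller one than between any other replicates, and each pair may be 1 sample measured in repeat libraries. Their counts were summed and each pair was counted as 1 sample, written replicate 1-2, before any gene was called. This departs from the design fixed beforehand, which had 4 samples per group at E18.5. The result of that design is given beside the E18.5 counts.

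Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and groups were compared by the quasi-likelihood test with Benjamini-Hochberg adjustment, at a threshold of 0.05 with no minimum fold change. Each knockout was compared with its controls at the same age in a model of its own. The difference between the Figla effects at P0 and E18.5, and P0 against E18.5 in controls, were tested in 1 model of all Figla samples. CPM in the text are on TMM-scaled library sizes, except those given for every library, which are on the total count. Where a group had no counts, the fold is a lower bound from a floor of 3 counts over the group, which falls by construction when a sample of that group is left out. Where it had 1 to 3 counts, the ratio of scaled counts is given with its 95% counting interval. Overlaps of calls were tested with Fisher's exact test, one-sided, over genes tested in both comparisons.

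Gene lists numbered 22: oocyte transcription factors, zona pellucida and oocyte secreted proteins, maternal effect genes with the subcortical maternal complex, oocyte RNA-binding and translation factors, oocyte receptors and growth genes, meiotic prophase, germ cell pluripotency genes, the piRNA pathway, testis-associated genes, Y-linked genes, granulosa, Sertoli, stromal, steroidogenic, surface epithelium, mesonephric, endothelial, macrophage and erythroid markers, p53 targets and death genes, proliferation genes and the Notch pathway. Each was tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists. The named genes are Figla, Lhx8, Sohlh1, Sohlh2 and Nobox in each knockout comparison; the 6 largest rises and 6 largest falls past the threshold with a mean of at least 1 CPM and no overlap between the groups; and the 2 called members of each list with the smallest adjusted p. Unnamed transcripts (Gm numbers and Rik clones) were counted and not named under the rule. Other genes that the text names as called members of a list, as examples of an overlap or as test genes were chosen after their values were seen. The result of 1 gene that the rule names is not reported here. Symbols came from the reference annotation by gene identifier, for 49326 of 49585 identifiers; 132 identifiers share a symbol.

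The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a minimum log2 fold change of 1, all Figla samples in 1 model, each sample left out in turn, the other groupings of the labels and, for Lhx8, the replicate number as a block. Each library as its own sample, the design fixed beforehand, became an alternative once the near-identical pairs were summed. Added after seeing the data were both E18.5 libraries numbered 3 left out, the order of deposit as a block in each Figla comparison, and the gene lists at E18.5 and for age without E18.5 control replicate 3. The steps were tested on simulated counts with the mean of each gene and the library sizes of the real samples, and the spread fitted by edgeR. In these, 100 genes changed 2-fold and 100 changed 4-fold. At E18.5, with 15826 genes in the step, edgeR recovered 19% of the 2-fold and 79% of the 4-fold changes with 6 false calls, where DESeq2 made 44. For Figla at P0, with 16972 genes, it recovered 58% and 92% with 18 false calls, where DESeq2 made 22. For Lhx8 at P0, with 14966 genes, it recovered 43% and 83% with 6 false calls, where DESeq2 made 15. In each simulation camera found the planted list and called 0 of 40 lists of unchanged genes. The simulation set no correlation between genes, so this cannot show whether the preset correlation holds for the real lists. For Figla at P0 the estimated correlation ran from -0.066 for Sertoli markers to 0.983 for erythroid markers.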

Results

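Gene expression was measured by RNA-seq in mouse ovaries lacking Figla or Lhx8, both of which encode transcription factors of oocytes, to follow how they act on oocyte growth and differentiation around birth. The Figla set held 4 control and 4 knockout libraries at E18.5 and 3 of each at P0. The Lhx8 set held 3 control and 3 knockout libraries at P0. Total counts ranged from 5583392 to 13408022 in the Figla libraries, with 25114 to 27940 genes seen, and from 8297204 to 9978350 in the Lhx8 libraries, with 21080 to 21702 genes seen. The ribosomal-type transcript CT010467.1 took 0.573% to 3.97% of Figla counts, and mitochondrial genes took 1.66% to 3.31% of Figla counts and 5.47% to 6.52% of Lhx8 counts. Intervals and floors given for counts cover counting error only. At E18.5, control replicates 1 and 2 and knockout replicates 1 and 2 were near-identical pairs, which differed by far less than any other replicates, though by more than sampling noise, and each pair was counted as 1 sample, which left 3 samples per group.

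Figla (ENSMUSG00000030001, GRCm38 chromosome 6, 86016171 to 86020996) was low in every library named as a knockout. At E18.5 it stood at 23.9, 20.5, 3.94 and 27.2 CPM (counts scaled to library size) in control replicates 1 to 4 and at 0.722, 0.961, 1.24 and 1.56 in knockout replicates 1 to 4. At P0 it stood at 32.5, 35.5 and 39.5 in controls and 0.175, 0.647 and 0.295 in knockouts. The order follows the library names in 14 of 14 Figla libraries, including the 6 whose titles name the other genotype. Lhx8 (ENSMUSG00000096225, chromosome 3, 154306294 to 154330659) stood at 90, 101 and 89.4 CPM in the libraries of the Lhx8 set named as controls and at 18.1, 31 and 23 in those named as knockouts. These libraries count the 3' end of transcripts and the labels do not give the deleted part of Lhx8, so this level may not check the label. The direction of every Lhx8 result rests on the library names, and grouping by title would turn each sign. Maternal effect genes argue against the titles. Of 18 tested, 17 were lower in the Lhx8 libraries named as knockouts (median log2 fold change -4.58). Under the titles these would be low in control ovaries. In the Figla set at P0, 15 of 15 tested were higher in controls than in knockouts.

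**Figure D1:**
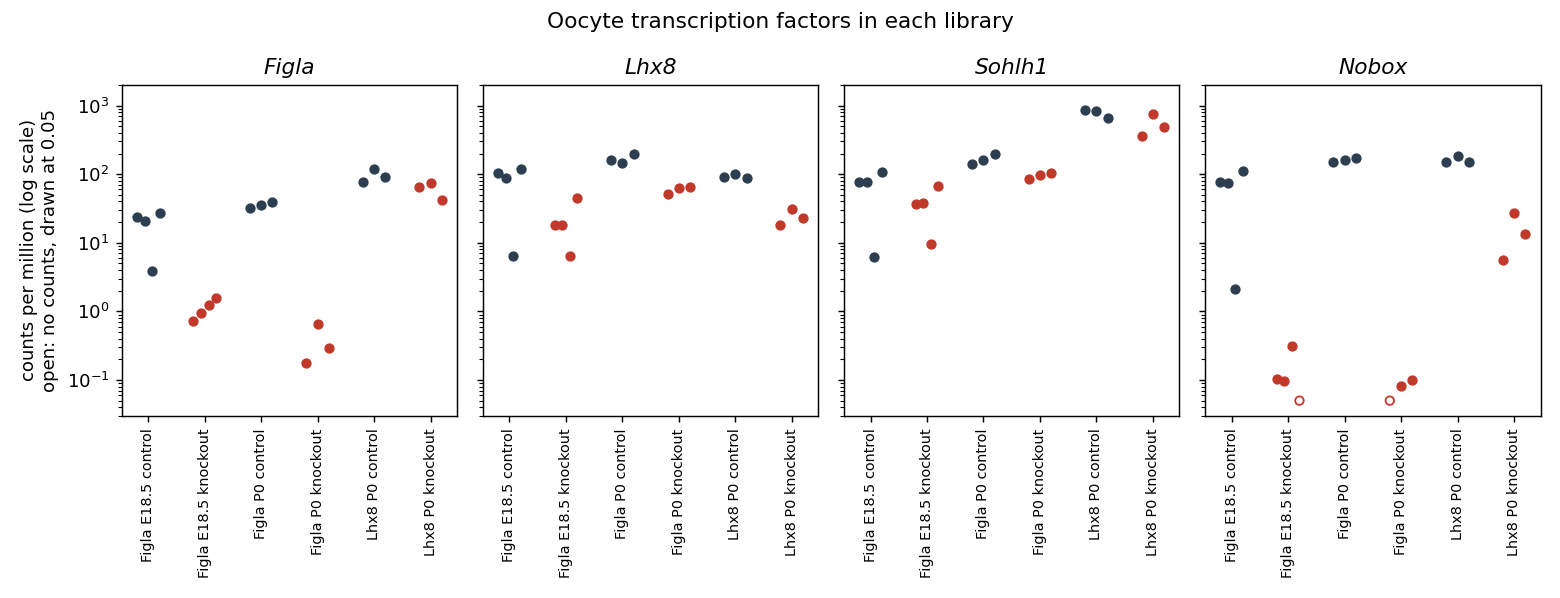
CPM of Figla, Lhx8, Sohlh1 and Nobox in each of the 20 libraries, on a log axis, grouped by set, age and genotype as the library is named; each point is 1 library, knockouts in red, and open points had no counts. Figla lies at 1.56 or below in each Figla knockout library, and E18.5 control replicate 3, at 3.94, lies between these and the other Figla controls.

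At E18.5, Figla and its fellow oocyte factor Nobox were lower in every Figla knockout sample than in every control. Neither passed edgeR's adjusted test of 3 samples against 3 without a block. Nobox averaged 0.141 ± 0.166 CPM in knockouts and 61.8 ± 54.3 in controls (SD, n = 3 samples each), with a log2 fold change of -8.86 (SE 1.62, adjusted p = 0.411). Figla averaged 1.24 ± 0.364 and 17.6 ± 12, with a log2 fold change of -3.91 (SE 0.71, adjusted p = 0.411). With every sample kept, both were called by DESeq2, with no filter on low counts, in 1 model of all Figla samples, with each library as its own sample, and with the order of deposit as a block, chosen after the data were seen. Adjusted p in these fits ran from 4.94e-07 to 0.0466 for Figla and from 1.08e-05 to 0.0429 for Nobox, while with RLE scaling it was 0.411 for both. The log2 fold changes of Lhx8, Sohlh1 and Sohlh2 were -1.66, -0.70 and -0.47, each with an adjusted p of 1. Control replicate 3 set much of this spread: Nobox stood at 2.15 CPM there and at 75.7, 74.7 and 111 in control replicates 1, 2 and 4, and Lhx8 at 6.45 against 103, 88.7 and 121. That library is also the shallowest, and its title names a knockout.

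Of 16131 genes tested at E18.5 with edgeR's quasi-likelihood test, 1 was lower and 0 were higher, while 607 had an unadjusted p under 0.05. The gene was Gm44601, named here after its value was seen, with a log2 fold change of -6.85 (SE 0.40, adjusted p = 0.00332). DESeq2 called 21 higher and 98 lower. In counts simulated for this comparison it made 44 false calls where edgeR made 6. It also recovered 42% of 2-fold and 86% of 4-fold changes, where edgeR recovered 19% and 79%. The simulation used the spread fitted by edgeR and held no sample like control replicate 3, so it does not settle which calls hold. With 4 libraries per group, the design fixed before the near-identical pairs were found, edgeR called 34 lower. With the order of deposit as a block, it called 3 higher and 25 lower. Without control replicate 3 it called 89 genes, each of them lower. Without both samples numbered 3, a choice made after the data were seen, it called 18 lower. Without knockout replicate 3 it called 0, and without knockout replicate 4 it called 2. Groups did not overlap for 1185 genes, 7.35% of those tested, where chance gives 10% if the 6 samples are exchangeable, which was not shown.

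The values below come from the fit without control replicate 3, with 2 control samples left and knockout replicate 3 kept. That knockout had a median log2 ratio of -1.036 to the other knockouts over Figla, Lhx8, Sohlh1 and Nobox. The groups of this fit are therefore not balanced for what sets the samples numbered 3 apart. Zp2, which encodes a protein of the egg coat, had 0 counts in knockouts and 589 in controls, at least 257-fold lower. Vrtn was at least 117-fold and Trim61 at least 83-fold lower. Nobox fell by 9.43 on the log2 scale (adjusted p = 0.00313), Pramef12 by 8.96 and Figla by 4.37 (adjusted p = 0.00623); over all alternatives the adjusted p ranged from 2.39e-06 to 1 for Nobox and from 4.94e-07 to 1 for Figla. Sycp2l had 1 count against 426, a control to knockout ratio of 558 (95% interval 99.7 to 22100). The maternal effect genes Nlrp4f and Tcl1 fell by 8.78 and 6.82, the receptor gene Kit by 2.77, the oocyte p53 family member Trp63 by 4.93, Lsm14b by 1.26 and the piRNA methyltransferase Henmt1 by 2.24. Trim75 had 2 counts against 110, a ratio of 72.1 (95% interval 19.5 to 603). Zp2, Vrtn, Trim61, Nlrp4f, Tcl1, Sycp2l and Trim75 did not pass the count filter with all samples. Of 88 such genes also tested in Figla knockouts at P0, 88 were lower there too (9.38 expected; Fisher's exact p = 3.84e-87), a test chosen after the data were seen.

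**Figure D2:**
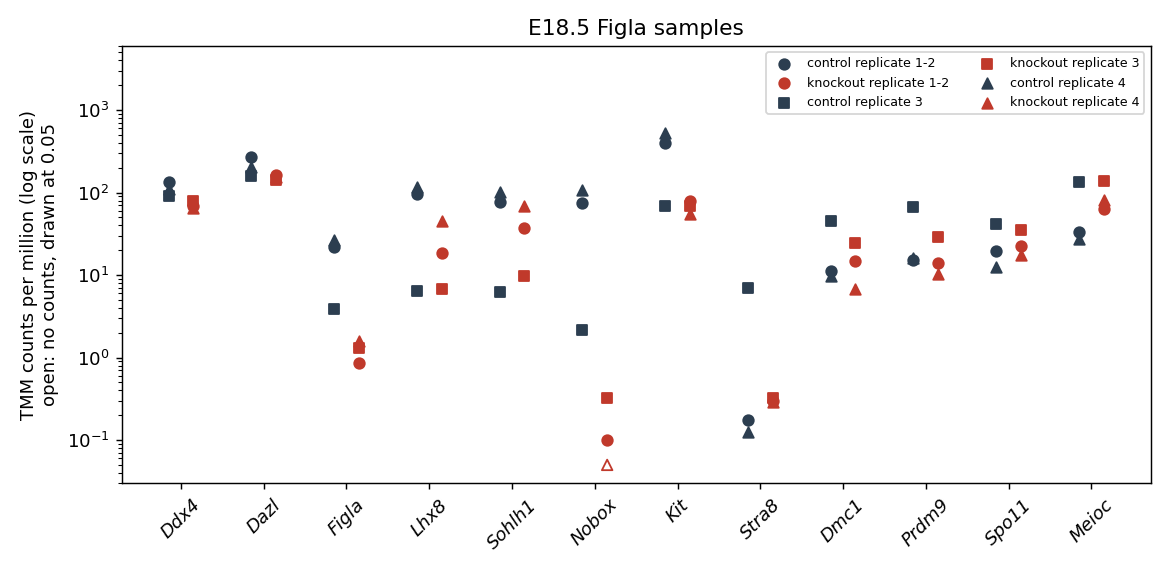
TMM CPM of 12 germ cell genes, chosen after their values were seen, in the 6 E18.5 Figla samples, on a log axis; each point is 1 sample, shaped by replicate and red for knockouts, and open points had no counts. Control replicate 3 lies below the other controls for Figla, Lhx8, Sohlh1, Nobox and Kit, and above them for Stra8, at 6.95 against 0.174 and 0.125.

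Camera called 5 germ cell gene lists lower at E18.5, with 0 members past the threshold over all genes in any list (edgeR; DESeq2 and unadjusted counts over all genes as above). Pluripotency genes (median log2 fold change 0.175 over 6, camera adjusted p = 0.34) and receptor and growth genes (median 0.05 over 17, adjusted p = 0.644) were not among them. Camera called the piRNA pathway lower (median log2 fold change -0.56 over 17 genes, adjusted p = 1.64e-06; adjusted p = 0.356 with an estimated correlation). It called meiotic prophase genes lower (median -0.31 over 34, adjusted p = 1.17e-05; adjusted p = 0.278 with an estimated correlation), though not without control replicate 3 (adjusted p = 0.129). Oocyte transcription factors (median -0.47 over 9, adjusted p = 0.000127), maternal effect genes (median -0.70 over 5, adjusted p = 0.000414) and RNA-binding factors (median -0.38 over 13, adjusted p = 0.000219) were called lower, each with adjusted p = 0.278 with an estimated correlation. Adjusted over the list alone, 2 transcription factors, 1 maternal effect gene, 2 RNA-binding factors and 2 piRNA genes fell. Of 15 p53 targets and death genes, 1 fell and 1 rose adjusted over the list alone. Erythroid markers were called higher, with a median of 1.16 over 7 genes and 7 of 7 past the threshold adjusted over the list alone (adjusted p = 2.78e-09; adjusted p = 0.278 with an estimated correlation). Macrophage markers (median 0.30, adjusted p = 0.000783), granulosa markers (median 0.18, adjusted p = 0.00404) and proliferation genes (median 0.29, adjusted p = 0.00936) were called higher, with adjusted p = 0.278, 0.278 and 0.63 with an estimated correlation. Proliferation genes were not called without control replicate 3 (adjusted p = 0.0749). The other 11 lists tested were not called (camera adjusted p from 0.109 to 0.907), and the median, mean and camera direction did not share a sign for receptor, stromal, duct, p53 and Notch genes. Of the zona pellucida and secreted protein list only Gdf9, at -0.69, and Bmp6, at 0.14 (adjusted p = 1 for both), passed the count filter, too few for a list test. Without control replicate 3, 4 of 12 maternal effect genes fell (median -4.74, camera adjusted p = 6.6e-18), as did 1 of 4 zona pellucida and secreted protein genes (median -3.32, adjusted p = 1.81e-05) and 2 of 20 receptor and growth genes (median -0.09, adjusted p = 0.000337). With an estimated correlation these had adjusted p = 0.127, 0.227 and 0.127. The count filter asks for fewer samples in this fit, so genes could enter that were high in the remaining controls alone. The maternal effect list grew from 5 to 12 tested genes and the receptor list from 17 to 20. The larger falls are set in part by this entry, so these list tests are no further support for a fall.

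At P0, Figla knockout ovaries had lost nearly all transcripts of the egg coat genes and of Nobox. Zp2 had 0 counts in knockouts and 3503 in controls, at least 1110-fold lower, and Zp3 and Zp1 were at least 315-fold and 188-fold lower, or 167-fold and 122-fold without control replicate 3. Nobox had 2 counts against 5887, a ratio of 2800 (95% interval 776 to 23200). In GRCm38, Nobox (ENSMUSG00000029736) lies on chromosome 6 from 43303674 to 43309554, Zp1 on chromosome 19 from 10914287 to 10920632, Zp2 on chromosome 7 from 120126772 to 120145291 and Zp3 on chromosome 5 from 135980099 to 135988624. Vrtn and the G protein-coupled receptor gene Gpr143 were at least 218-fold and 198-fold lower. Figla fell by 6.54 on the log2 scale (SE 0.29, adjusted p = 5.42e-07), Sohlh2 by 1.41 (SE 0.14, adjusted p = 0.000111) and Sohlh1, a germline helix-loop-helix factor, by 0.80 (SE 0.14, adjusted p = 0.00282), with each of 3 knockouts below each of 3 controls. Lhx8 fell from 169 ± 28.5 to 59.8 ± 6.08 CPM (SD, n = 3; adjusted p = 5.42e-05).

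The largest rises at P0 were of genes near the floor in controls. Fezf2, a forebrain transcription factor gene, had 225 counts in knockouts and 3 in controls, a control to knockout ratio of 0.0127 (95% interval 0.0026 to 0.0376), and Cplx3, a synaptic complexin gene, had 122 and 2, a ratio of 0.0156 (0.00187 to 0.0576). The counts of Fezf2 in controls were all in replicate 3 and those of Cplx3 all in replicate 1, without which they were at least 50-fold and 28.4-fold higher in knockouts. The ratio of Fezf2 without control replicate 1 was 0.0191 (0.00391 to 0.0565), and that of Cplx3 without control replicate 3 was 0.0246 (0.00295 to 0.0908). Tbx18 rose from 0.415 ± 0.155 to 11.4 ± 2.35 CPM (SD, n = 3), the proneural factor gene Neurog2 from 0.165 ± 0.0794 to 2.78 ± 1.12, Abcc12 from 0.145 ± 0.13 to 2.09 ± 0.375, and Lman1l from 0.193 ± 0.125 to 2.76 ± 0.616. Their adjusted p ranged from 9.83e-06 for Tbx18 to 0.0018 for Abcc12. Cplx3 (57599992 to 57606281) and Lman1l (57607085 to 57620774) lie close together on the minus strand of chromosome 9. Their rises may therefore not be separate, which was not tested.

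Many members of the oocyte gene lists fell in Figla knockouts at P0. Of 15 maternal effect genes tested, 15 fell, 15 adjusted over the list alone, with a median log2 fold change of -7.00, or -5.89 with genes that had no counts in a group at their bound (camera adjusted p = 9.24e-17; adjusted p = 0.2 with an estimated correlation). Among them, Tcl1 had 2 counts against 2284, a ratio of 1090 (301 to 8990), and Nlrp4f fell by 8.78. Of 7 zona pellucida and secreted protein genes 6 fell, 6 adjusted over the list alone, and the growth factor gene Bmp6 had a log2 fold change of 0.03 (median -9.05, or -6.05 with bounds; camera adjusted p = 4.7e-07; adjusted p = 0.222 with an estimated correlation). Of 10 oocyte transcription factors 8 fell, 9 adjusted over the list alone (median -1.26, camera adjusted p = 6.92e-09; adjusted p = 0.2 with an estimated correlation). Of 13 RNA-binding factors 9 fell, 9 adjusted over the list alone, including Elavl2 by 3.35 and Cpeb1 by 1.70 (median -0.58, camera adjusted p = 3.41e-05; adjusted p = 0.288 with an estimated correlation). Of 22 receptor and growth genes 11 fell and 2 rose, 13 and 3 adjusted over the list alone. Kit, the receptor for Kit ligand, fell by 3.67 and the gap junction gene Gja4 by 2.15 (median -0.59, camera adjusted p = 1.42e-05; adjusted p = 0.2 with an estimated correlation).

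Some members of the meiotic and piRNA lists also fell in Figla knockouts at P0. Of 18 piRNA genes 10 fell, 13 with 1 rise adjusted over the list alone, led by Tdrd5 at -1.82 and Tdrd1 at -2.21 (median -0.61, camera adjusted p = 4.12e-06; adjusted p = 0.222 with an estimated correlation). Of 35 meiotic prophase genes 6 fell and 1 rose, 8 and 2 adjusted over the list alone, with a median of -0.20 that camera did not call (adjusted p = 0.056). Terb1 fell by 1.18 and Syce2 by 0.99. Of 10 germ cell pluripotency genes 4 fell and 1 rose, the same counts as adjusted over the list alone. Pou5f1 had 3 counts against 370, a ratio of 117 (39.9 to 572), which was 75.6 (25.4 to 370) without control replicate 3 and 247 (44.1 to 9780) without knockout replicate 3, and Sox2 rose by 3.07 (camera adjusted p = 0.167). Of 16 proliferation genes 7 fell, 9 adjusted over the list alone, with Birc5 at -1.27 and Bub1 at -0.85 (camera adjusted p = 0.000284; adjusted p = 0.476 with an estimated correlation). Of 14 Notch pathway genes 2 fell and 1 rose, 6 and 2 adjusted over the list alone. The falls were of the ligand genes Jag2, by 2.84 (SE 0.11, adjusted p = 2.27e-07), and Jag1 (adjusted p = 0.000565; camera adjusted p = 0.547). Of 15 p53 targets and death genes 2 fell and 2 rose, 3 and 3 adjusted over the list alone, with Trp63 at -6.43 and Trp53inp1 at 0.49 (camera adjusted p = 0.705). Of 21 testis-associated genes 2 fell, 2 adjusted over the list alone, Dmrtb1 by 2.79 and Tuba3a by 1.96 (camera adjusted p = 0.936).

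Some markers of somatic cells rose modestly in Figla knockouts at P0. These are relative levels in whole ovaries. A lower share of germ cell RNA would raise them with no change within somatic cells, and the 2 were not told apart. Of 13 stromal markers 7 rose, 8 adjusted over the list alone, with Acta2 at 0.50 and Pdgfra at 0.64 (camera adjusted p = 0.00038; adjusted p = 0.2 with an estimated correlation). Of 20 granulosa markers 4 rose, 11 adjusted over the list alone. Kitl, which encodes Kit ligand, rose by 0.80 and Fst, the follistatin gene, by 0.87 (camera adjusted p = 0.000546; adjusted p = 0.25 with an estimated correlation). Of 10 endothelial markers 4 rose, 6 adjusted over the list alone, with Cdh5 at 0.66 and Tie1 at 0.61 (camera adjusted p = 0.00197; adjusted p = 0.382 with an estimated correlation). Of 10 macrophage markers 2 rose, 5 adjusted over the list alone, Csf1r by 0.46 and Lyz2 by 0.72 (camera adjusted p = 0.000284; adjusted p = 0.2 with an estimated correlation). Of 9 steroidogenic markers, Hsd3b6 fell by 4.42 and Lhcgr rose by 1.33, 1 and 3 adjusted over the list alone (camera adjusted p = 0.0528). The surface epithelium marker Cdh1 fell by 0.61, 1 of 10 and 0 adjusted over the list alone (edgeR; camera adjusted p = 0.706). Camera did not call the list of 6 duct markers (adjusted p = 0.706). Of 9 Sertoli and 7 erythroid markers none was called by edgeR (camera adjusted p = 0.425 and 0.705). The median and the camera direction had opposite signs for testis-associated genes (median 0.08) and the Notch pathway (median 0.03), and the median and mean for these lists, duct markers (0.37 and -0.07), erythroid markers (0.09 and -0.16) and p53 targets (0.18 and -0.35). Y-linked genes did not pass the count filter in any comparison.

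In all, 17321 genes were tested in Figla knockouts at P0, of which 887 were higher and 1880 lower by edgeR's quasi-likelihood test, 188 and 720 of them at least 2-fold. Groups did not overlap for 6171 genes, or 35.6%, where chance gives 10% for exchangeable samples. Without knockout replicate 2 the counts were 404 and 1201, without knockout replicate 3 they were 273 and 1150, and without control replicate 3 there were 551 higher. With the order of deposit as a block, chosen after the data were seen, the counts were 2019 and 2661. In 1 model with the E18.5 samples the counts were 265 and 1098, and 12 of 48 genes named by the rule were not called. These were Lhx8, Sohlh1 and Tdrd1 (adjusted p = 0.242, 0.547 and 0.0547; over all alternatives 1.56e-28 to 0.242, 6.38e-09 to 0.547 and 1.03e-65 to 0.0547), and Fst, Acta2, Pdgfra, Lhcgr, Cdh1, Tie1, Csf1r, Lyz2 and Trp53inp1 (adjusted p from 0.0502 to 0.606; over all alternatives 1.32e-09 to 0.606). Grouping by title gave 0 and 0 with edgeR. Leaving out 1 sample ended the call of Csf1r in 6 of 6 cases (adjusted p up to 0.162), Cdh1 and Lyz2 in 5 (up to 0.153 and 0.165), Cdh5 and Tie1 in 4 (up to 0.0942 and 0.164), Lhcgr and Trp53inp1 in 3 (up to 0.0907 and 0.122), Pdgfra in 2 (up to 0.09), and Acta2 and Fst in 1 (up to 0.0742 and 0.0517). Without knockout replicate 2, Figla stood at -7.21, and without control replicate 3, Hsd3b6 stood at -3.36 and Abcc12 at 3.20. Without control replicate 1, Abcc12 stood at 4.45 and Lman1l at 4.33.

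**Figure D3:**
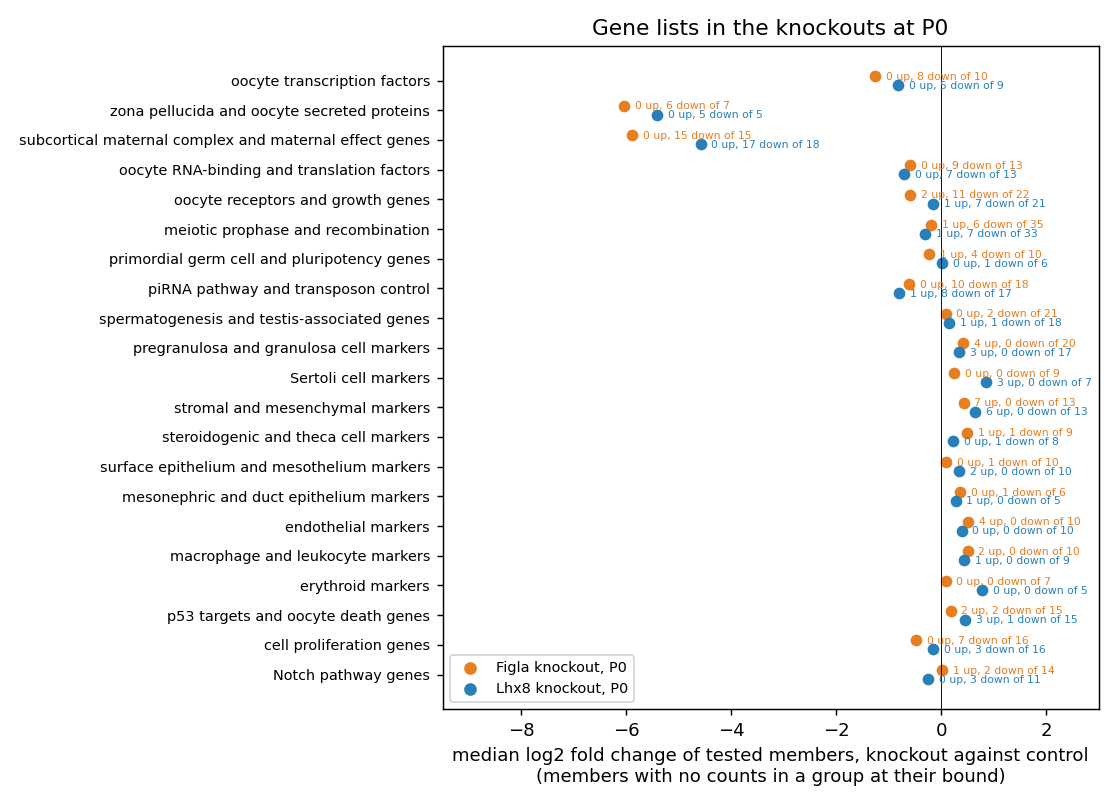
Median log2 fold change of the tested members of each gene list in Figla and Lhx8 knockouts at P0, with members that had no counts in a group at their bound; each marker is 1 list in 1 knockout, and the numbers beside it count called members. Zona pellucida genes lie at -6.05 and -5.41 and maternal effect genes at -5.89 and -4.58, below every other list in both knockouts.

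Egg coat and maternal effect transcripts also fell in Lhx8 knockout ovaries at P0. Zp1 had 0 counts in knockouts and 222 in controls, at least 74.5-fold lower, and the F-box gene Fbxw26, Umodl1 and Gpr143 were at least 144-fold, 61.7-fold and 60.4-fold lower. Fbxw18 had 1 count against 890, a ratio of 896 (95% interval 160 to 35400), and Nlrp4f had 3 against 1374, a ratio of 461 (157 to 2240). The 1 count of Fbxw18 was in knockout replicate 1 and the 3 of Nlrp4f in knockout replicate 2, without which they were at least 190-fold and 300-fold lower. Without knockout replicate 2 the ratio of Fbxw18 was 584 (105 to 23100), and without knockout replicate 1 that of Nlrp4f was 293 (100 to 1420). Counts of the Fbxw and Nlrp4 families are uncertain because their copies share sequence. Lhx8 itself fell by 2.01 on the log2 scale (SE 0.20, adjusted p = 0.000206), Nobox by 3.44 (SE 0.43, adjusted p = 0.000922) and Sohlh2 by 1.01 (SE 0.26, adjusted p = 0.0357). Figla, at -0.70 (SE 0.21, adjusted p = 0.0632), and Sohlh1, at -0.61 (SE 0.24, adjusted p = 0.141), did not pass the threshold.

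Among the rises in Lhx8 knockouts was Dmrt1, a member of the testis-associated list, at 4.54 (SE 0.83, adjusted p = 0.00729). It stood at 4.29, 42.8 and 11.3 CPM in the 3 knockouts and at 0.822 ± 0.312 in controls (SD, n = 3). Without knockout replicate 2 it stood at 3.19 (adjusted p = 0.0076; over all alternatives 1.78e-22 to 0.0493), below Esx1 at 4.20. With all samples, Esx1 rose by 4.47, Dennd1c by 3.98, the retinoic acid binding protein gene Crabp2 by 3.93, Slc12a8 by 3.26 and the nuclear receptor gene Nr4a1 by 3.12, with adjusted p from 0.000123 for Crabp2 to 0.0151 for Nr4a1.

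Of 18 maternal effect genes tested in Lhx8 knockouts 17 fell, 18 adjusted over the list alone, with a median log2 fold change of -4.58 (camera adjusted p = 1.47e-19; adjusted p = 0.151 with an estimated correlation). Padi6, a component of oocyte lattices, fell by 7.54 (SE 0.24, adjusted p = 1.15e-07), while Dppa3 fell from 449 ± 95.9 to 67.5 ± 27.2 CPM (SD, n = 3). Of 5 zona pellucida and secreted protein genes 5 fell, 5 adjusted over the list alone, with Zp3 at -7.62 and the growth factor gene Gdf9 at -4.06 (median -7.62, or -5.41 with bounds; camera adjusted p = 7.18e-09; adjusted p = 0.151 with an estimated correlation). Of 9 oocyte transcription factors 5 fell, 8 adjusted over the list alone (camera adjusted p = 6.99e-05; adjusted p = 0.238 with an estimated correlation). Of 13 RNA-binding factors 7 fell, 8 adjusted over the list alone, with Elavl2 at -2.86 and Gtsf1 at -2.54 (camera adjusted p = 6.99e-05; adjusted p = 0.238 with an estimated correlation). Of 21 receptor and growth genes 7 fell and 1 rose, 7 and 3 adjusted over the list alone, with Gja4 at -2.12 and Kit at -2.83 (camera adjusted p = 0.0174; adjusted p = 0.233 with an estimated correlation). Of 17 piRNA genes 8 fell and 1 rose, 10 and 1 adjusted over the list alone, with Tdrd1 at -2.14 and Exd1 at -2.07 (camera adjusted p = 7.64e-05; adjusted p = 0.284 with an estimated correlation). Of 33 meiotic genes 7 fell and 1 rose, 10 and 1 adjusted over the list alone, with Terb1 at -1.34 and Syce2 at -0.98 (camera adjusted p = 0.00205; adjusted p = 0.366 with an estimated correlation).

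Among the other lists in Lhx8 knockouts, 3 of 16 proliferation genes fell, 3 adjusted over the list alone, with Birc5 at -1.26 and Plk1 at -0.85 (camera adjusted p = 0.0321; adjusted p = 0.415 with an estimated correlation). Of 11 Notch pathway genes 3 fell, 3 with 1 rise adjusted over the list alone, with Jag2 at -2.59 and Heyl at -1.48 (camera adjusted p = 0.127). Of 15 p53 targets and death genes 3 rose and 1 fell, 6 and 2 adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a rose by 0.79, and Trp63 fell by 4.57 (camera adjusted p = 0.119). Zfp42 fell by 1.41, 1 of 6 pluripotency genes, with 2 falls and 1 rise adjusted over the list alone (median 0.02 with a camera direction of lower; adjusted p = 0.411). Of 18 testis-associated genes Dmrt1 rose and Dmrtb1 fell by 1.37, the same counts adjusted over the list alone (camera adjusted p = 0.593).

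Some somatic markers rose in Lhx8 knockouts as well, again as relative levels that a lower share of germ cell RNA would also raise. Of 13 stromal markers 6 rose, 9 adjusted over the list alone, with Col3a1 at 0.72 and Lum at 0.82 (camera adjusted p = 7.92e-05; adjusted p = 0.238 with an estimated correlation). Of 17 granulosa markers 3 rose, 8 adjusted over the list alone, with Kitl at 0.88 and Gja1 at 0.82 (camera adjusted p = 0.00355; adjusted p = 0.182 with an estimated correlation). Of 7 Sertoli cell markers 3 rose, 5 adjusted over the list alone, with Aard at 0.86 and Sox9, a factor of Sertoli and duct cells, at 0.85 (camera adjusted p = 0.0237; adjusted p = 0.284 with an estimated correlation). Of 9 macrophage markers C1qc rose by 1.06, with 3 adjusted over the list alone (camera adjusted p = 0.007; adjusted p = 0.284 with an estimated correlation). Of 10 surface epithelium markers Cdh1 rose by 1.17 and Krt19 by 0.56, 2 adjusted over the list alone (camera adjusted p = 0.0321; adjusted p = 0.366 with an estimated correlation). None of 10 endothelial markers was called by edgeR, while camera called the list higher (adjusted p = 0.0321; adjusted p = 0.284 with an estimated correlation). Emx2 rose by 0.55, 1 of 5 duct markers and 1 adjusted over the list alone (camera adjusted p = 0.411). Hsd3b6 fell by 3.36, 1 of 8 steroidogenic markers, with 1 fall and 1 rise adjusted over the list alone (median 0.23 and mean -0.02; camera adjusted p = 0.708). None of 5 erythroid markers was called by edgeR, and 3 rose adjusted over the list alone (camera adjusted p = 0.116).

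In all, 15274 genes were tested in Lhx8 knockouts, of which 468 were higher and 1114 lower by edgeR's quasi-likelihood test, 184 and 574 of them at least 2-fold. Groups did not overlap for 5150 genes, or 33.7%, where chance gives 10%. Without control replicate 1 the counts were 114 and 619, without control replicate 2 they were 99 and 531, and without control replicate 3 they were 204 and 707. Leaving out 1 sample ended the call of Sohlh2, Krt19 and Emx2 in 5 of 6 cases (adjusted p up to 0.148, 0.131 and 0.135), Dmrtb1, Gja1 and Aard in 4 (up to 0.107, 0.136 and 0.0998), Sox9 in 3 (up to 0.11), Zfp42, Cdh1, C1qc and Cdkn1a in 2 (up to 0.0602, 0.0593, 0.0742 and 0.0619) and Nr4a1, Lum and Heyl in 1 (up to 0.058, 0.0524 and 0.0636), and brought Figla and Sohlh1 past the threshold in 1 case each (adjusted p = 0.0423 and 0.0234). Without knockout replicate 2, Nobox stood at -4.15 and Zp3 at -8.52, and without control replicate 2, Nr4a1 stood at 3.83.

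Most genes that fell in Lhx8 knockouts also fell in Figla knockouts at P0. Over 14185 genes tested in both, 762 were lower in both where independent lists would share 125 (odds ratio 35.9, Fisher's exact test), or 44.5% of the Figla falls and 73.6% of the Lhx8 falls. They include Zp1, Zp3, Gpr143, Nlrp4f, Padi6, Kit, Gja4, Elavl2, Tdrd1, Jag2 and Trp63. Another 179 were higher in both where 24.9 would be shared (Fisher's exact p = 3.47e-110), among them Kitl and Nr4a1. The meiotic gene Meioc, named after its values were seen, rose from 30.7 ± 24.6 to 93.5 ± 10 CPM in Figla knockouts and from 11.8 ± 1.89 to 30.4 ± 8.4 in Lhx8 knockouts (SD, n = 3). Opposite calls numbered 7 for genes lower in Figla and higher in Lhx8 knockouts, such as Dennd1c, at -1.41 and 3.98, and Cdh1, at -0.61 and 1.17, and 1 in the other direction, Bend4, at 0.78 and -1.15. With the Lhx8 groups turned as its titles have them, these 7 would be the genes lower in both and this 1 the gene higher in both. Whether these differ between the knockouts was not tested, because the libraries were made with different kits. Across genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.756 and a Spearman rho of 0.638. The knockouts share no control libraries.

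**Figure D4:**
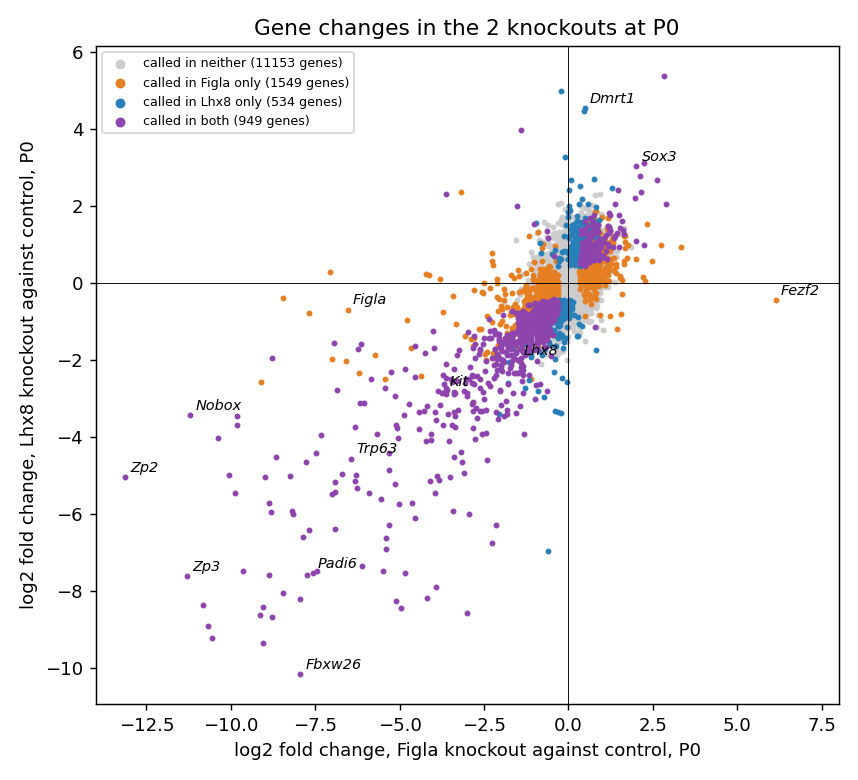
Log2 fold change of each of 14185 genes in Figla knockouts at P0 (horizontal axis) and Lhx8 knockouts at P0 (vertical axis), coloured by whether edgeR called it in 1, both or neither; each point is 1 gene, and fitted values of genes with no counts in a group are no measure of size. Of these, 949 were called in both, 762 of them lower in both and 179 higher in both.

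The Figla effect was not shown to differ between E18.5 and P0. The interaction of age and genotype, tested in 18379 genes with edgeR, gave 0 higher and 0 lower genes, with 977 at an unadjusted p under 0.05 and a smallest adjusted p of 0.913. DESeq2 gave 0 and 0, with 1098 at an unadjusted p under 0.05. With the order of deposit as a block within each age, edgeR gave 0 and 0, with 2316 at an unadjusted p under 0.05.

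In control ovaries, oocyte gene lists were higher at P0 than at E18.5, though no single gene passed the test with edgeR. Maternal effect genes had a median log2 difference of 2.12 over 18 genes, 16 of which rose adjusted over the list alone (camera adjusted p = 1.89e-08; adjusted p = 0.295 with an estimated correlation). Zona pellucida genes had a median of 2.35 over 7 genes, 6 of which rose adjusted over the list alone (camera adjusted p = 1.6e-05; adjusted p = 0.295 with an estimated correlation). The piRNA pathway (median 0.58, camera adjusted p = 1.6e-05) and pluripotency genes (median 1.04, adjusted p = 0.000293) were also called higher, with adjusted p = 0.312 and 0.295 with an estimated correlation. So were oocyte transcription factors (median 1.06, adjusted p = 0.00145), RNA-binding factors (median 0.52, adjusted p = 0.000823), receptor and growth genes (median 0.35, adjusted p = 0.0166) and surface epithelium markers (median 0.35, adjusted p = 0.0106), with adjusted p = 0.295, 0.295, 0.312 and 0.295 with an estimated correlation. Markers of other cell types were called lower: endothelial (median -0.43, adjusted p = 0.0106), macrophage (median -0.43, adjusted p = 0.0448) and erythroid (median -0.70, adjusted p = 0.0448), with adjusted p = 0.312, 0.295 and 0.63 with an estimated correlation. In all, camera called 8 lists higher and 3 lower, and 0 with an estimated correlation. The median, mean and camera direction did not share a sign for testis-associated, Sertoli, steroidogenic, p53, proliferation and Notch genes, none of which was called. The E18.5 controls include replicate 3, in which oocyte factor genes were low. Without it, a choice made after the data were seen, maternal effect genes had a median of 1.59 over 19 genes, 11 of which rose adjusted over the list alone (camera adjusted p = 3.31e-09), and zona pellucida genes a median of 1.95 over 7, 5 of which rose (adjusted p = 2.66e-06). The piRNA pathway had a median of 0.33 (adjusted p = 0.000338) and pluripotency genes 1.12 (adjusted p = 4e-04), and each of these 4 lists had adjusted p = 0.194 with an estimated correlation. Endothelial markers had a median of -0.44 (adjusted p = 0.00915; adjusted p = 0.297 with an estimated correlation). Macrophage markers were not called without it (adjusted p = 0.0554), and stromal markers were called lower (median -0.30, adjusted p = 0.0398; adjusted p = 0.194 with an estimated correlation). Without it edgeR called 0 genes higher and 0 lower, with 3053 at an unadjusted p under 0.05. With edgeR, 0 of 18379 genes were higher and 0 lower, with 4254 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0605. DESeq2 called 1034 higher and 517 lower. Without E18.5 control replicate 4 edgeR called 439 and 117, and without E18.5 knockout sample 1-2, which shares the model, it called 281 and 225. Age was not separated from collection day or litter, which the labels do not give.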

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

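Both E18.5 libraries numbered 3 left out, the order of deposit as a block, and lists without E18.5 control replicate 3 were chosen after the data were seen. Each library as its own sample is the design fixed beforehand, made an alternative once the near-identical pairs were seen. The other alternatives were chosen before the data were examined. RLE scaling kept 2657 of 2767 calls for Figla at P0 and 1567 of 1582 for Lhx8, and DESeq2 kept 2644 and 1556. The cause of the changes in count below was not tested, except where fewer samples, another grouping or a stricter threshold sets them by construction.

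At E18.5, against 0 genes higher and 1 lower, DESeq2 called 21 and 98 (82.4% lower, against 100% of 1 gene), no filter on low counts 63 and 166, and all Figla samples in 1 model 53 lower. Each library as its own sample gave 34 lower, leaving out both libraries numbered 3 gave 18 lower, and the order of deposit as a block gave 3 and 25. Libraries with agreeing labels, 1 control sample against 2 knockouts, gave 518 and 564, and the lone control was assumed to vary like the knockouts. Grouping by title, which splits the first 4 libraries from the last 4, gave 398 and 695. Leaving out 1 sample gave 0 higher and 0 to 89 lower.

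For Figla at P0, against 887 higher and 1880 lower, no filter gave 1379 higher, the 2-fold minimum 188 and 720, 1 model 265 and 1098, agreeing labels 562 higher, the order of deposit as a block 2019 and 2661, and grouping by title 0 and 0. Agreeing labels ended the calls of Lhcgr, Cdh1, Csf1r and Trp53inp1, and DESeq2 and no filter that of Csf1r. Leaving out 1 sample gave 273 to 1042 higher and 1150 to 1840 lower. For Lhx8, against 468 and 1114, no filter gave 970 and 1712 and the 2-fold minimum 184 and 574. Grouping by title gave 1114 and 468 and turned the log2 fold change of Lhx8 to 2.01, since it swaps the groups. Leaving out 1 sample gave 99 to 469 higher and 531 to 1021 lower. Genes higher in both knockouts, 179, were 271 with DESeq2 and 31 with the 2-fold minimum, which left 363 of 762 lower in both.

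With the Lhx8 replicate number as a block, 217 genes were higher and 714 lower, and Sohlh2, Dmrtb1, Gja1, Aard, Krt19 and Emx2 were not called. Same-numbered samples did not deviate together (correlations from -0.154 to 0.047 over 3 pairs, and 0 samples correlated best with their own number), so the numbers were not taken to pair the samples. Figla samples with the same number in order of deposit did deviate together, in a check made after the blocked calls were seen. Correlations were 0.259 to 0.575 at E18.5 and 0.288 to 0.392 at P0 over 3 pairs each, and 6 of 6 samples correlated best with their own number at each age. The library names also run in sequence through the Figla set, a control and a knockout by turns, so same-numbered samples are neighbours. No label says that neighbours are pairs, so the numbers were not used as a pairing. If they are pairs, the main Figla fits, which lack the order of deposit as a block, ignore them. With that block at E18.5, Figla and Nobox were called (adjusted p = 0.0466 and 0.00694; over all alternatives 4.94e-07 to 1 and 2.39e-06 to 1). At P0 it kept 2767 of 2767 calls, with 56.9% of its calls lower against 67.9%.

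With an estimated correlation, camera called 0 lists lower and 0 higher in each knockout comparison and for age. Without E18.5 control replicate 3 it called 8 lists higher and 3 lower for age, as many as with all samples, though macrophage markers left the lists called lower and stromal markers entered them. For the interaction of age and genotype, no filter gave 5 higher and 58 lower, and leaving out 1 sample, or the order of deposit as a block within each age, gave 0 and 0 with edgeR (2316 genes at an unadjusted p under 0.05 with the block). A block within each age leaves age itself with no estimate. For age, against 0 and 0, DESeq2 gave 1034 and 517, no filter 829 and 423, and each library as its own sample 864 and 626. Leaving out 1 sample gave 0 to 439 higher and 0 to 225 lower. Depth limits genes near the floor: a count of 0 allows up to 0.224 CPM in the deepest library and 0.537 CPM in the shallowest.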

Other observations

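The tests of an explanation were chosen after the result was seen, except that of nervous tissue and the splits of the samples. Genes shared between the knockouts also rose outside the lists fixed beforehand, and those named here were chosen after their values were seen. Slc2a3, a glucose transporter gene, rose by 2.15 on the log2 scale in Figla knockouts and 2.36 in Lhx8 knockouts at P0 (edgeR adjusted p = 7.67e-06 and 0.000343). The transcription factor gene Sox3 rose by 2.01 and 3.03, the muscle enolase gene Eno3 by 1.97 and 2.21, and the kinesin gene Kif5a by 2.88 and 2.05. In each case the 3 knockouts lay above the 3 controls.

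Oocyte factor genes were low in E18.5 control replicate 3, with a median log2 ratio to the other controls of -3.857 over Figla, Lhx8, Sohlh1 and Nobox. A knockout library under a control label would hold Figla at the knockout level. The Figla rate of control replicate 3 was 3.61 times the pooled knockout rate (95% interval 2.02 to 6.3), against 1.45 for the highest single knockout. Its Nobox rate was 17.7 times (5.37 to 75.4). Other oocyte genes stood near their level in knockout replicate 3, with Lhx8 at 6.42 CPM against 6.8, Kit at 69 against 68.3 and Nlrp5 at 0.178 against 0.648. The intervals cover counting error only and the title names a knockout, so a wrong label is not excluded. Fewer germ cells would lower meiotic and piRNA genes alike, but their median log2 ratio was -0.096 over 51 genes (interquartile range 1.41). These lists share members, such as Dmc1 and Prdm9, with the early prophase genes below, which were mostly higher in this library. The median therefore cannot exclude fewer germ cells. Ddx4 stood at 92 CPM against 135 and 112 in the other controls, and Dazl at 157 against 269 and 203. An ovary at an earlier stage of meiotic prophase may account for the low oocyte factor genes. Of 19 early prophase genes, 14 lay above both other control samples (median 0.728, interquartile range 1.83). With so few samples, a part of the genes would lie above both by chance. Stra8, which marks meiotic entry, stood at 6.95 CPM against 0.174 and 0.125. Knockout replicate 3 differed from the other knockouts in the same directions by median (0.582 for early prophase genes and -1.036 for the 4 factors). Its Stra8, however, stood at 0.324 CPM, near the 0.301 and 0.286 of the other knockouts. The earlier stage stays open, because the spread of the genes exceeds their median.

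Fewer germ cells in the knockout ovaries could lower oocyte genes at P0. As the whole cause, a loss of all germ cells alike would lower meiotic and piRNA genes by about as much as the called zona and maternal effect genes. But their medians were -0.343 against -7.577, or -6.045 with genes that had no counts in knockouts at their bound, in Figla knockouts (interquartile range 0.753 over 53 genes). In Lhx8 knockouts they were -0.397 against -5.023, with or without bounds (interquartile range 0.797). The germ cell marker Ddx4 had log2 fold changes of -0.84 and -0.94 (adjusted p = 0.000388 and 0.00559), and Dazl of -0.45 and -0.14 (adjusted p = 0.034 and 0.607). Loss of some germ cells stays open as a part of the fall, as does the loss of the factors themselves. The comparison cannot exclude a loss of only those germ cells that express zona and maternal effect genes. Those genes were also chosen as called, while the meiotic and piRNA genes were not.

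Regulators of neural development, such as Fezf2 and Neurog2, were among the largest rises in Figla knockouts at P0. Nervous tissue in the libraries would bring abundant neuronal transcripts, whose median log2 fold change was 0.052 over 20 genes (interquartile range 0.616). Of 30 listed regulators tested, 10 rose, where 1.54 were expected, and 3 fell, but 7 of those that rose had been seen before the list was written. Without these, 3 of 23 rose where 1.18 were expected (one-sided Fisher's exact p = 0.111), so a rise of such regulators as a group was not shown and no biological explanation was tested.

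The 6 samples of each knockout comparison make 10 splits, too few for a share under 0.05. The splits treat the samples as exchangeable, which was not shown, and Figla samples with the same number in order of deposit deviated together. The real split was 1 of 10 in each to call as many genes: 1 gene at E18.5 where the highest other split called 0, 2767 for Figla at P0 where it called 0, and 1582 for Lhx8 where it called 0. For age, with 0 genes called, 10 of 10 splits called as many, and the highest other called 0. For the interaction, with 0 genes called by edgeR, 50 of 50 splits drawn called as many, and the highest other called 1356. Those splits mix the ages within each genotype, so differences between ages enter the interaction. A real count of 0 fixes the outcome, so for age and the interaction the splits decide nothing about chance.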
